A study of Mus musculus with 6 samples.

How the data were processed

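RNA was measured in 6 libraries of mouse primary microglia, 3 that received vehicle and LPS and 3 that received C13 and LPS. Per the labels' protocols, poly-A RNA was captured on beads and libraries were made with a stranded mRNA kit. Reads were processed with TopHat2 2.1.0 and Cufflinks against mm10, per the submitters' processing notes, while the annotation, the Cufflinks version and the use of strand are not given in the sources used here. The deposited table holds 1 FPKM value per gene and library (fragments scaled to transcript length and library total), made by the authors, and every value column was matched to its sample by the sample's description. FPKM divides by an assumed transcript length and by the library total, so a library in which short or GC-rich transcripts are over-represented differs in FPKM from the others in a way that depends on length, and a fold change can be read only relative to the other genes of its library.

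The table held 24340 named genes after 1 emptied line was left out. The lowest value was 0.01 FPKM, shared by 52253 values and by 6808 genes in every library, and was taken as the floor at which undetected genes were listed. The symbols of 18 rows had been turned into dates, of which 12 were tested without being named. Of the tested genes 2524 shared their locus with another row, so that reads of overlapping genes cannot be told apart from the table alone. Gene positions and strands were taken, by symbol or by an older symbol that pointed to 1 gene, from GENCODE mouse release 21 on GRCm38, the assembly that UCSC names mm10. A match was found for 99.45% of the genes tested. The length and GC content of a gene are those of its longest annotated transcript.

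Read totals are not in the table. Depth was estimated from the size of the first step above the floor, which is worth 1 fragment, in genes with a single annotated transcript of at least 1500 nt and a locus of their own (86 to 104 genes in the step per library). It came to 8910000 to 11560000 fragments. The ratios of FPKM between libraries in 1266 low genes, which need no transcript length, gave depths of 1.21, 1.20, 1.26, 1.30 and 1.25 relative to vehicle replicate 1 for the other libraries in the order vehicle 2, vehicle 3, C13 1, C13 2 and C13 3. At these depths a transcript of 1 kb with 1 FPKM rests on 8.91 to 11.56 fragments, so values near 1 FPKM carry wide counting error. Cufflinks divides fragments among transcripts, and whole reads were not recovered for most genes, so no count test was run.

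Groups were taken from the sample titles. FPKM values were transformed to log2(FPKM + 1), genes with a mean of at least 1 FPKM over the 6 libraries were kept, and the groups were compared with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend, robust option off, two-sided). The p-values were adjusted by the Benjamini-Hochberg method over the 11412 genes with a threshold of 0.05. Every change given is on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 28 lists, beside an estimated correlation and fry. All 28 lists, the tests and the rule for named genes were fixed before the data were examined. The rule took, among genes past the threshold with groups that did not overlap, the 12 with the largest rise and the 12 with the largest fall, and where fewer than 12 passed in a direction, those that passed and then those with the smallest unadjusted p up to 5. It took the 4 members with the smallest p of each list past the threshold and 1 of each other list, and as values Mok, Tnf, Il6, Il1b, Ifnb1, Nos2 and Cxcl10. A few genes that the rule took, and a marker of a test chosen after the data were seen, are not reported here, and that test was run again without the marker. Chemokine genes other than Cxcl10 and Cxcl11, and the genes named for the comparison without vehicle replicate 2, were chosen after their values were seen.

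The fits were tested on simulated data made from the real means and spreads, with 200 of 11412 genes changed, in 5 runs. With all 6 libraries, 25.6% of genes raised by 0.5 and 19.2% of genes lowered by 0.5 on the log2 scale were recovered, 91.6% of those raised by 1 and 99.6% of those raised by 1.5, with 6.1% false calls among the genes called. Without vehicle replicate 2 the shares were 77.6%, 69.2%, 100% and 99.6%, with 4.5% false calls. A simulated list of 25 genes shifted by 0.4 was called in 5 of 5 runs and none of 140 unshifted lists was. Simulated genes varied independently, which favours camera's preset correlation. Within a gene all simulated libraries had the same spread, so no library stood apart as vehicle replicate 2 did. The recovered shares therefore need not hold for the real libraries, where Cyp1a1 and Hmox1, with changes of 1.12 and 1.02, did not pass.

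Alternatives tried were pseudocounts of 0.1 and 5, no filter and a minimum of 5 FPKM, quantile normalization, median-of-ratios scaling, rescaling to TPM, limma without the trend, its robust option, array weights, the replicate number as a block, a minimum change of 1, and each library left out in turn. A removal of the trend on transcript length and GC content from each library (natural splines with 5 degrees of freedom) was added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the figures.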

Results

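Poly-A RNA was sequenced from primary microglia, the resident macrophages of the brain, which were cultured from newborn C57BL/6 mice. The cells received 10 uM C13, a small molecule described by the submitters as an inhibitor of the kinase MOK, or its DMSO vehicle for 1 h and were then exposed for 5 h to 1 ug/ml lipopolysaccharide (LPS), a bacterial membrane component sensed through Toll-like receptor 4. There were 3 libraries per group, and every library had received LPS, so the comparison shows how LPS-exposed microglia differed with C13 and not what LPS did. The deposited table gave 24340 genes in FPKM, of which 11412 had a mean of at least 1 FPKM and were tested. The table held no read totals. The smallest steps between low FPKM values put the depth at about 8910000, 10790000 and 10740000 fragments for vehicle replicates 1, 2 and 3. For C13 replicates 1, 2 and 3 it was about 11310000, 11560000 and 11140000 fragments. Vehicle replicate 2 stood apart, with a median correlation of 0.969 with the other libraries across genes against 0.984 to 0.989 for the rest, and an FPKM sum of 634451 against 504674 to 534757. The labels call the samples biological replicates and name no culture or litter, so p-values measure the spread between these samples, part of which may be technical.

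The gene of the kinase that C13 is meant to inhibit was measured in every library. Mok (chromosome 12, 110807798 to 110840939, minus strand, GRCm38) lay below the limit for testing at 0.375 ± 0.114 FPKM with vehicle and 0.373 ± 0.139 FPKM with C13 (SD, n = 3). The list of MOK-family kinases, BET proteins and their cofactors did not pass its test (12 of 14 members measured, median change in log2(FPKM + 1) of 0.12, limma camera adjusted p = 0.189), and its median without vehicle replicate 2 was -0.02. These values concern RNA and carry no information on kinase activity.

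The main comparison asked how the RNA of LPS-exposed microglia differed between C13 and vehicle. Genes of the NRF2 antioxidant response rose as a list by a median of 0.42 in log2(FPKM + 1), while interferon-stimulated genes fell by a median of 0.26 and proinflammatory cytokine genes by a median of 0.33. These 3 list calls rest on camera with a preset correlation, and their adjusted p was 0.0693, 0.113 and 0.113 with an estimated correlation. No single gene passed the test over all genes with all 6 libraries. The genes with the smallest p on the higher side were Cyp1a1, a xenobiotic-metabolising cytochrome P450, Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, the antioxidant genes Srxn1 and Gclm, and the AMP deaminase gene Ampd3. Hmox1 had 572 ± 31.5 FPKM with vehicle and 1162 ± 90.5 FPKM with C13. Srxn1 had 51.8 ± 6.24 and 99.5 ± 2.92 FPKM. Gclm had 42.1 ± 2.65 and 79.9 ± 7.77 FPKM. Ampd3 had 8.07 ± 1.23 and 18.7 ± 1.52 FPKM. Cyp1a1 had 2.83 ± 0.219 and 7.35 ± 0.225 FPKM (SD, n = 3 each). On the lower side were the growth factor gene Hbegf, the involucrin gene Ivl, Il23a, which encodes a subunit of an inflammatory interleukin, the tryptophanyl-tRNA synthetase gene Wars and the cytokine gene Osm. Hbegf had 71.8 ± 3.69 FPKM with vehicle and 40.9 ± 3.70 FPKM with C13. Ivl had 10.4 ± 1.17 and 4.12 ± 0.80 FPKM, and Il23a 11.5 ± 0.736 and 6.10 ± 0.579 FPKM. Wars had 79.7 ± 2.50 and 53.1 ± 3.09 FPKM, and Osm 15.9 ± 2.03 and 8.09 ± 0.931 FPKM. In each of these 10 genes the 3 C13 libraries lay on one side of all 3 vehicle libraries, yet none passed. The lowest adjusted p was 0.0694, for Cyp1a1 (change in log2(FPKM + 1) of 1.12, SE 0.097), and the other 9 had adjusted p between 0.0798 and 0.17. Thus limma called 0 genes higher and 0 lower, with 293 higher and 544 lower at an unadjusted p under 0.05, where chance gives 571 in all. These 837 genes were fewer than the 903 of another split of the libraries, vehicle replicates 1 and 3 and C13 replicate 1 against the rest. The groups did not overlap in 779 genes higher and 1116 genes lower with C13, 16.6% of the genes tested, where chance gives 10%.

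The 10 genes are all annotated as protein-coding on GRCm38. Cyp1a1 lies on chromosome 9 (57687928 to 57703824), Hmox1 on chromosome 8 (75093621 to 75100589), Srxn1 on chromosome 2 (152105516 to 152111376), Gclm on chromosome 3 (122245557 to 122270732) and Ampd3 on chromosome 7 (110768206 to 110812405), each on the plus strand. Hbegf lies on chromosome 18 (36504927 to 36515805), Ivl on chromosome 3 (92570902 to 92573735), Il23a on chromosome 10 (128296139 to 128298752) and Wars on chromosome 12 (108860030 to 108894174), each on the minus strand, and Osm on the plus strand of chromosome 11 (4236420 to 4241026).

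The count of genes past the threshold depended on vehicle replicate 2. Without that library 47 genes rose and 122 fell, the 10 genes above among them. The 12 with the largest rise were, beside Cyp1a1, Hmox1, Srxn1, Ampd3 and Gclm, the quinone reductase gene Nqo1 (change of 0.78), the iron exporter gene Slc40a1 (0.81), Ddit4l, Zcchc5, Ramp3, Cdk20 and the microRNA gene Mir8112, which was listed at the lowest value of the table, 0.01 FPKM, in vehicle replicates 1 and 3. Beside Ivl, Hbegf, Osm and Il23a, the 12 with the largest fall were Ifit1bl1 (change of -0.90), Timd4 (-0.85), AA467197 (-0.85), the hyaluronan synthase gene Has2 (-0.82), Hsh2d (-0.81), Sdcbp2 (-0.80), the chemokine gene Ccl12 (-0.70) and Tagap (-0.70). These names followed the same rule, applied to a comparison that was singled out after the values were seen. The vehicle spread in that comparison rests on replicates 1 and 3 alone. Its median residual SD was 0.088, against 0.159 with all 6 libraries.

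**Figure D1:**
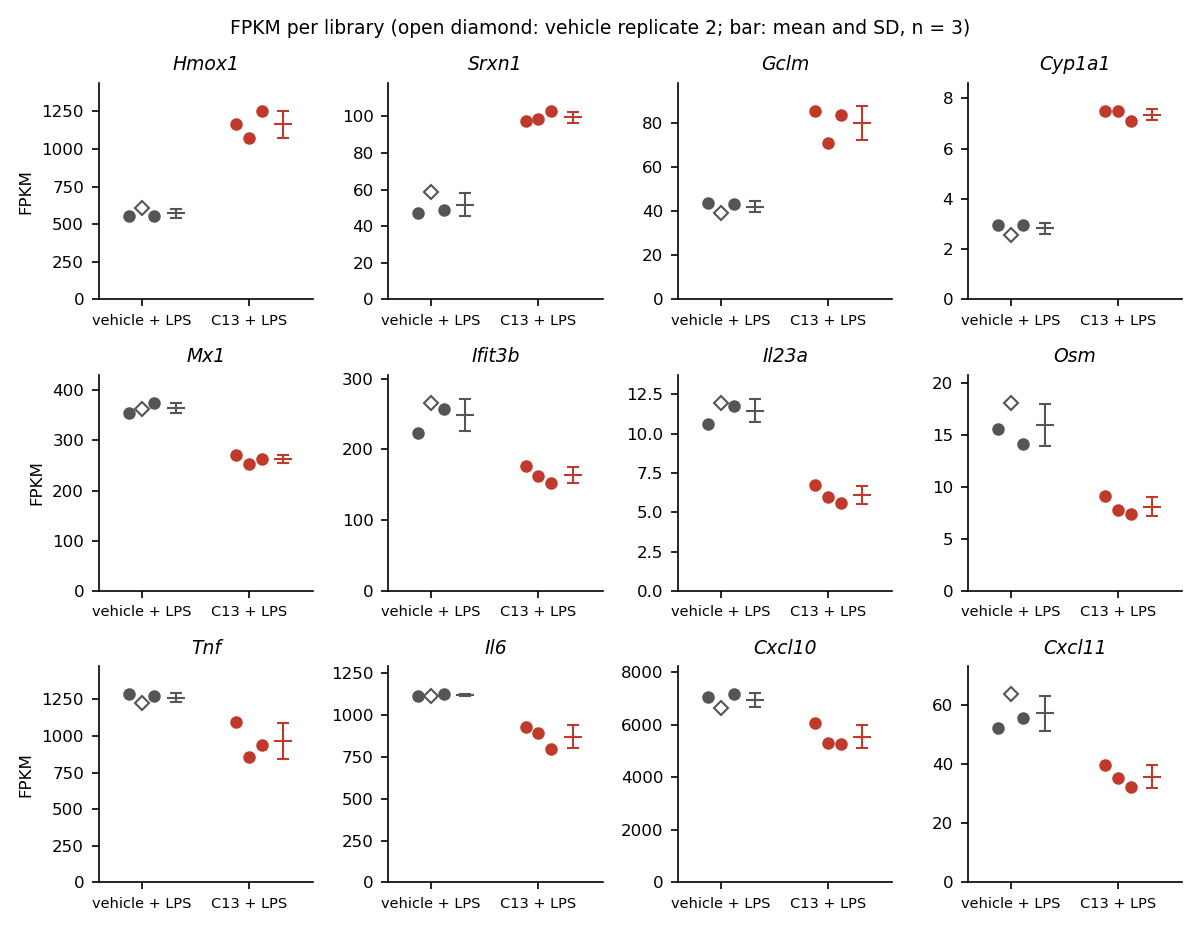
FPKM per library of 12 named genes in vehicle plus LPS (grey) and C13 plus LPS (red), with the mean and SD of 3 libraries beside the points and vehicle replicate 2 as an open diamond. Hmox1 lay at 572 ± 31.5 FPKM with vehicle and 1162 ± 90.5 FPKM with C13, and in each panel the groups did not overlap.

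Among the 28 gene lists fixed beforehand, 11 passed the camera test with a preset correlation between genes of 0.01, 3 on the higher and 8 on the lower side. No single member passed over all 11412 genes in any list, so the counts of members below are adjusted over the list alone, or are counts of members above or below 0. With the correlation estimated from the data 0 lists passed, and fry, which tests a list's genes without setting them against other genes, called 6, of which 5 were among the 11. Under quantile normalization the calls of interferon-stimulated genes, cytokines and antigen presentation were kept with smaller medians of -0.11, -0.17 and -0.16. With a pseudocount of 5 the medians of immediate early genes, cholesterol synthesis genes and astrocyte markers were -0.08, 0.11 and 0.27, with the calls kept.

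Targets of NRF2, the transcription factor that drives antioxidant and detoxification genes, rose as a list. Of its 26 members 25 were measured, 24 lay above 0, and 17 rose and 0 fell when adjusted over the list alone, leaving 8 that did not pass. The median change was 0.42 (camera adjusted p = 2.53e-20, and adjusted p = 0.0693 with an estimated correlation). Beside Hmox1, Srxn1 and Gclm the member with the smallest p was Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, with 8.48 ± 1.48 FPKM with vehicle and 15.8 ± 0.258 FPKM with C13 (SD, n = 3). The mean deviation of the list from the vehicle mean was 0.45, 0.44 and 0.52 in C13 replicates 1, 2 and 3 and between -0.04 and 0.07 in the vehicle libraries. Without vehicle replicate 2, 13 of its members rose over all genes tested and the median was 0.45. The camera adjusted p with an estimated correlation was then 0.232.

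Interferon-stimulated genes, which encode antiviral effectors and are switched on by interferon secreted after LPS, fell as a list. All 53 members were measured, 50 lay below 0, and 19 fell and 0 rose when adjusted over the list alone, with 34 not passing. The median change was -0.26 (camera adjusted p = 2.53e-20, and adjusted p = 0.113 with an estimated correlation), and in the C13 libraries the mean deviation of the list from the vehicle mean was -0.20, -0.31 and -0.29. Mx1 had 364 ± 10.3 FPKM with vehicle and 262 ± 8.05 FPKM with C13. Mx2, annotated as a polymorphic pseudogene, had 106 ± 8.13 and 73.2 ± 2.61 FPKM. Ifit3b had 249 ± 22.5 and 164 ± 11.8 FPKM. Ifi205 had 317 ± 15.6 and 234 ± 12.4 FPKM (SD, n = 3). Ifit3b and Ifi205 have close paralogs between which reads can be split, so their single values are less certain than the list. Without vehicle replicate 2, 17 members fell over all genes tested and the median stayed at -0.26, with a camera adjusted p of 0.325 with an estimated correlation.

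The list of interferons, their receptors and signalling factors also passed on the lower side (12 of 19 measured, 9 below 0, median change -0.08, camera adjusted p = 0.00735, and adjusted p = 0.278 with an estimated correlation). Adjusted over the list alone, Irf5 and Irf8 fell and the other 10 did not pass. The receptor genes Ifnar1, Ifnar2, Ifngr1 and Ifngr2 changed by only 0.05, -0.002, 0.12 and -0.07, so the call does not describe the receptors. Irf5, a transcription factor of the Toll-like receptor response, had 150 ± 10.4 FPKM with vehicle and 109 ± 6.57 FPKM with C13. Irf8, a factor of microglial identity, had 35.8 ± 2.93 and 25.9 ± 2.78 FPKM. Irf1 had 136 ± 9.86 and 112 ± 4.21 FPKM. The signalling inhibitor gene Socs1 had 77.5 ± 11.97 and 59.1 ± 3.63 FPKM. Ifnb1, the interferon beta gene, had 14.9 ± 6.96 FPKM with vehicle and 7.43 ± 1.65 FPKM with C13 and its groups overlapped, since vehicle replicate 1 had 8.08 FPKM and C13 replicate 3 had 9.34 FPKM. The list did not pass without vehicle replicate 2 (median -0.13, adjusted p = 0.107), with quantile normalization (median -0.03, adjusted p = 0.135) or with array weights (adjusted p = 0.0764). Its median was -0.05 without C13 replicate 2 and -0.12 without C13 replicate 1, and its median was 0.05 when libraries were rescaled to TPM, or -0.07 relative to the shift of 0.13 that this scaling gave the median of all genes, with the call kept.

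Proinflammatory cytokine genes fell as a list (20 of 21 measured, 18 below 0, median change -0.33, camera adjusted p = 5.88e-12, and adjusted p = 0.113 with an estimated correlation). Adjusted over the list alone, 10 fell, 0 rose and 10 did not pass. Beside Il23a and Osm the members with the smallest p were Il27, with 248 ± 28.9 FPKM with vehicle and 152 ± 25.2 FPKM with C13, and the growth factor gene Csf2, with 7.39 ± 1.22 and 3.49 ± 1.02 FPKM. Tnf, which encodes tumour necrosis factor, had 1261 ± 29.8 and 965 ± 120 FPKM. Il6 had 1116 ± 5.99 and 871 ± 69.1 FPKM, and both were among the 10 that fell over the list alone. Il1b had 1890 ± 183 and 1534 ± 36.2 FPKM and did not pass. Over all genes tested the adjusted p of Tnf, Il6 and Il1b was 0.509, 0.469 and 0.63.

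Chemokine genes did not pass as a list (22 measured, median change -0.21, camera adjusted p = 0.0911), and their members went both ways. Without vehicle replicate 2 the median was -0.09 (adjusted p = 0.398), while the list passed without C13 replicate 1, with rescaling to TPM and without the intensity trend. Adjusted over the list alone, Cxcl1, Cxcl3 and Cxcl5 rose, Ccl3, Ccl12, Ccl22, Cxcl9 and Cxcl11 fell, and 14 did not pass. Cxcl11, annotated as a polymorphic pseudogene, had the smallest p of the list, with 57.0 ± 5.89 FPKM with vehicle and 35.7 ± 3.79 FPKM with C13. Cxcl10, the most abundant of the chemokines named here, had 6951 ± 269 and 5548 ± 441 FPKM, with an adjusted p of 0.649 over all genes tested. By contrast Cxcl1, a neutrophil attractant named here after its values were seen, had 603 ± 30.5 and 793 ± 21.3 FPKM.

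NF-kappaB targets and feedback genes fell as a list (29 measured, 24 below 0, median change -0.13, camera adjusted p = 8.65e-05, and adjusted p = 0.145 with an estimated correlation), with 0 of 29 past the threshold over the list alone. The costimulatory receptor gene Cd40 had 311 ± 26.7 FPKM with vehicle and 217 ± 29.1 FPKM with C13. Traf1 had 62.5 ± 11.5 and 44.6 ± 2.42 FPKM. Bcl3 had 27.8 ± 6.49 and 19.7 ± 1.80 FPKM. The adhesion molecule gene Icam1 had 345 ± 17.4 and 286 ± 40.5 FPKM. The call was lost with quantile normalization (median -0.06, adjusted p = 0.127), and with rescaling to TPM the median was -0.001, or -0.13 relative to the shift of all genes, with the call kept. Immediate early and MAPK feedback genes, which follow growth factor and stress kinase signals, fell as well (31 of 32 measured, 23 below 0, median change -0.13, camera adjusted p = 1.67e-04, and adjusted p = 0.145 with an estimated correlation). The median was -0.08 after removal of a trend on transcript length and GC content, and -0.01 with rescaling to TPM, or -0.14 relative to the shift of all genes, with the call kept. Over the list alone Dusp2, Dusp5, Btg2 and Egr1 fell and 27 members did not pass. The phosphatase gene Dusp2 had 29.9 ± 2.12 and 19.2 ± 2.47 FPKM. Dusp5 had 32.0 ± 2.70 and 23.3 ± 0.866 FPKM. Btg2 had 28.96 ± 1.29 and 22.5 ± 0.463 FPKM. The transcription factor gene Egr1 had 34.5 ± 3.47 and 25.02 ± 1.38 FPKM.

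Genes of antigen presentation fell as a list (22 of 25 measured, 19 below 0, median change -0.25, camera adjusted p = 1.26e-07, and adjusted p = 0.278 with an estimated correlation), with 0 of 22 past the threshold over the list alone. The peptide transporter genes Tap1 and Tap2 had 235 ± 12.2 and 120 ± 16.5 FPKM with vehicle and 186 ± 9.51 and 94.1 ± 4.29 FPKM with C13. Cd86, a costimulatory ligand gene, had 25.3 ± 2.102 and 19.2 ± 3.21 FPKM, and H2-Q4, one of a family of similar class I genes between which reads can be split, had 243 ± 31.3 and 180 ± 5.69 FPKM. In vehicle replicate 2 the list lay 0.21 above the vehicle mean, and without that library the median change was -0.17. The integrated stress and unfolded protein response genes fell as a list (31 measured, 25 below 0, median change -0.13, camera adjusted p = 3.34e-04, and adjusted p = 0.278 with an estimated correlation), again with 0 members past the threshold over the list alone. Herpud1 had 72.3 ± 1.91 and 58.2 ± 6.03 FPKM. Ppp1r15a had 31.2 ± 1.96 and 25.3 ± 1.56 FPKM. The transcription factor gene Ddit3 had 53.5 ± 15.2 and 37.6 ± 1.51 FPKM. Xbp1 had 82.4 ± 4.75 and 71.5 ± 1.55 FPKM. The median of the stress response list was -0.09 without vehicle replicate 2, its call was lost with quantile normalization (adjusted p = 0.405), and its median was 0.005 with rescaling to TPM, or -0.12 relative to the shift of all genes, with the call kept.

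The list fixed as markers of homeostatic microglia passed on the lower side (24 of 26 measured, 18 below 0, median change -0.13, camera adjusted p = 0.0132, and adjusted p = 0.276 with an estimated correlation), with 0 past the threshold over the list alone. The list did not pass without vehicle replicate 2 (median -0.05, adjusted p = 0.0611), without C13 replicate 2 (adjusted p = 0.0518) or among genes with a mean of at least 5 FPKM (adjusted p = 0.0625), and its median was 0.004 with rescaling to TPM, or -0.12 relative to the shift of all genes, with the call kept. The member with the smallest p was the fatty acid receptor gene Gpr84. Whether it marks that state in these cells cannot be told, since no library lacked LPS. Gpr84 had 120 ± 11.8 FPKM with vehicle and 86.7 ± 6.997 FPKM with C13. By contrast Tmem119, Cx3cr1, Sall1 and Csf1r changed by only 0.05, -0.02, -0.05 and 0.08, so the call does not describe every marker of that state. The purinergic receptor genes P2ry12 and P2ry13 had 2.54 ± 0.582 and 3.44 ± 0.193 FPKM with vehicle and 1.71 ± 0.370 and 2.81 ± 0.250 FPKM with C13.

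Cholesterol synthesis and uptake genes rose as a list (24 of 25 measured, 20 above 0, median change 0.19, camera adjusted p = 2.11e-05, and adjusted p = 0.278 with an estimated correlation), with 0 past the threshold over the list alone. Msmo1 had 11.96 ± 0.689 FPKM with vehicle and 17.2 ± 3.35 FPKM with C13. Hmgcs1 had 7.94 ± 1.596 and 12.8 ± 3.75 FPKM. Idi1 had 6.54 ± 0.690 and 8.86 ± 1.73 FPKM. The mean deviation of the list was 0.34 in C13 replicate 2, against 0.07 and 0.18 in C13 replicates 1 and 3, and the median change without C13 replicate 2 was 0.12.

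The same library held the highest astrocyte signal. Astrocyte markers passed on the higher side (14 of 20 measured, 12 above 0, median change 0.50, camera adjusted p = 9.72e-06, and adjusted p = 0.278 with an estimated correlation), with 0 past the threshold over the list alone. Their mean deviation from the vehicle mean was 1.20 in C13 replicate 2 and 0.14 and 0.34 in C13 replicates 1 and 3, and the median change without C13 replicate 2 was 0.29. Gfap, the astrocyte filament gene, had 5.80, 35.6 and 8.79 FPKM in C13 replicates 1, 2 and 3 and 4.22 ± 1.30 FPKM with vehicle. Mlc1 had 2.24, 7.62 and 2.53 FPKM in the C13 libraries and 1.42 ± 0.226 FPKM with vehicle. The gap junction gene Gja1 had 39.9 ± 6.52 and 49.9 ± 2.47 FPKM. The glutamate transporter gene Slc1a2 had 0.999 ± 0.20 and 1.61 ± 0.371 FPKM. Markers of the other cell types a glial culture can hold did not pass. The oligodendrocyte lineage list had a median of 0.04 (adjusted p = 0.497), led by Pdgfra with 3.46 ± 0.440 and 6.00 ± 1.79 FPKM. It too was highest in C13 replicate 2, with a mean deviation of 0.37 against 0.04 and 0.20 in C13 replicates 1 and 3, and its median was 0.14 without vehicle replicate 2. The neuron list had 3 of 17 members measured and a median of -0.10 (adjusted p = 0.511), which turned to 0.02 without vehicle replicate 2. Stmn2 had 83.4 ± 12.7 and 74.8 ± 5.93 FPKM. Fibroblast and vascular markers had a median of -0.02 (adjusted p = 0.924), and Acta2, the smooth muscle actin gene, was abundant in both groups at 1487 ± 266 and 1200 ± 86.7 FPKM. Border macrophage, monocyte and neutrophil markers had a median of 0.03 (adjusted p = 0.687), with the lectin gene Clec4n at 53.5 ± 7.98 and 73.0 ± 4.72 FPKM. Clec4n passed over all genes without vehicle replicate 2 (change of 0.56, limma adjusted p = 0.0187), where the medians of the border macrophage and fibroblast lists were 0.08 and -0.07.

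**Figure D2:**
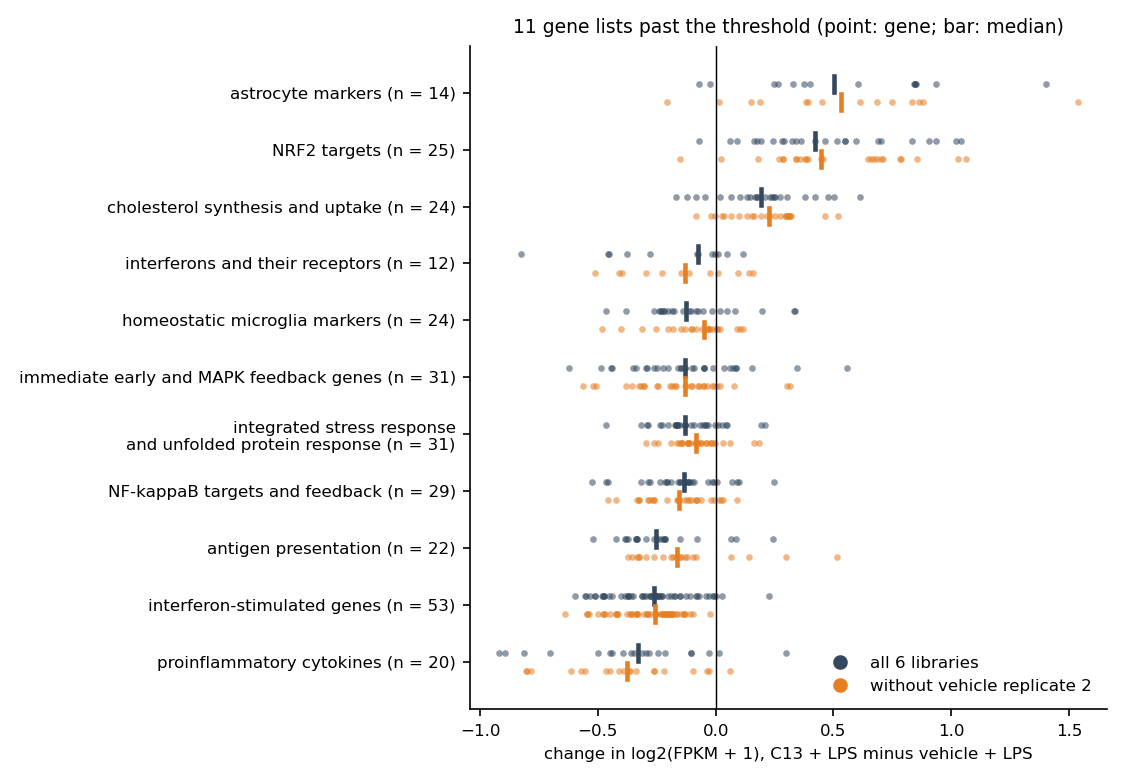
Change in log2(FPKM + 1), C13 plus LPS minus vehicle plus LPS, of each measured member (points) of the 11 lists past the threshold, with the list median as a vertical bar, from all 6 libraries (dark) and without vehicle replicate 2 (orange). The NRF2 targets had a median of 0.42 and the interferon-stimulated genes one of -0.26, close to the medians without that library, while the astrocyte markers, highest in C13 replicate 2, spread up to 1.40 with all libraries.

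The remaining lists did not pass. Inflammatory effectors had a median of 0.00 (28 measured, adjusted p = 0.113), and passed without vehicle replicate 2 with a median of -0.14 (adjusted p = 0.0235, and 0.328 with an estimated correlation). The plasminogen activator gene Plau had 63.1 ± 1.64 FPKM with vehicle and 50.5 ± 2.62 FPKM with C13. Nos2, the inducible nitric oxide synthase gene, had 276 ± 17.0 and 214 ± 32.8 FPKM with an adjusted p of 0.578 over all genes. Anti-inflammatory genes had a median of -0.13 (20 of 25 measured, adjusted p = 0.102) and passed without vehicle replicate 2 (median -0.20, adjusted p = 0.002, and 0.325 with an estimated correlation). Over the list alone, 2 rose and 4 fell, among them Il1rn, the interleukin 1 receptor antagonist gene, with 294 ± 20.4 and 196 ± 17.0 FPKM. The Toll-like receptor pathway had a median of 0.06 (30 of 31 measured, adjusted p = 0.333), with the adaptor gene Myd88 at 142 ± 10.0 and 111 ± 3.21 FPKM. BET-dependent genes had a median of 0.10 (9 of 13 measured, adjusted p = 0.497), although Myc fell over the list alone, from 50.7 ± 3.83 to 39.6 ± 0.651 FPKM. Hexim1, of the MOK and BET list, had 8.26 ± 0.507 and 9.23 ± 0.183 FPKM. Disease-associated microglia markers had a median of -0.08 (24 measured, adjusted p = 0.111, Cst7 at 45.6 ± 7.21 and 34.5 ± 3.09 FPKM), and heat shock genes one of -0.10 (16 measured, adjusted p = 0.111, Dnajb1 at 25.03 ± 1.54 and 20.6 ± 0.721 FPKM). LXR targets had a median of 0.08 (18 measured, adjusted p = 0.0799), and passed in 7 alternatives, among them removal of the length and GC trend and leaving out C13 replicate 1 or C13 replicate 3. Cell cycle genes had a median of 0.02 (32 measured, adjusted p = 0.88, Mcm6 at 39.2 ± 2.16 and 32.4 ± 0.838 FPKM). The p53 targets had a median of -0.06 (20 measured, adjusted p = 0.511, Cdkn1a at 461 ± 20.5 and 403 ± 23.3 FPKM). For glycolysis and hypoxia genes the median was -0.02 while the mean and the test lay on the higher side (26 of 27 measured, mean 0.03, adjusted p = 0.702, Bnip3 at 14.9 ± 0.340 and 21.4 ± 2.48 FPKM). The lysosome and autophagy list had a median of -0.06 (30 measured, adjusted p = 0.702), with the NRF2 target Sqstm1 at 483 ± 35.1 and 587 ± 16.8 FPKM. Without vehicle replicate 2 the medians of the Toll-like receptor pathway and BET-dependent genes turned to -0.03 and -0.05, and those of the glycolysis and lysosome lists to 0.06 and 0.01. Those of disease-associated microglia markers and heat shock genes shrank to -0.005 and -0.04.

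**Figure D3:**
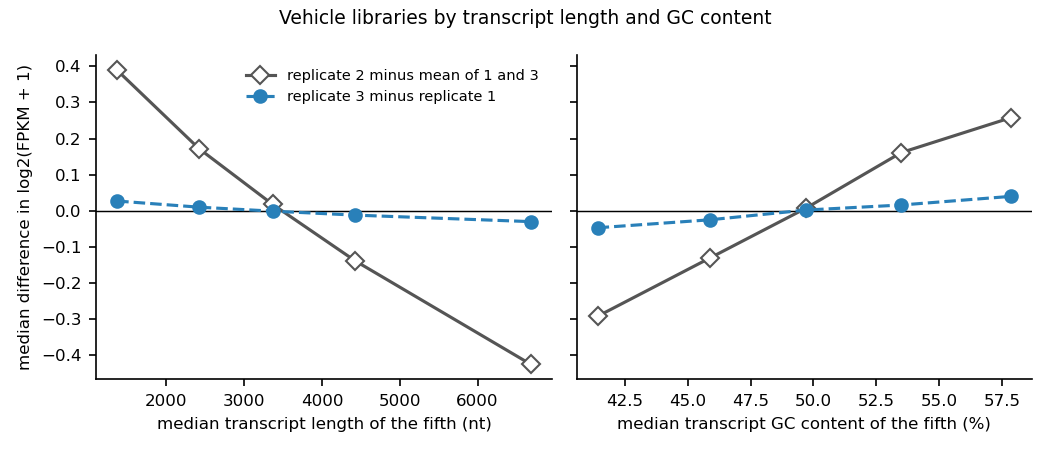
Median difference in log2(FPKM + 1) between vehicle libraries for genes in 5 bins of equal size by transcript length (left, nt) and by transcript GC content (right, percent), for replicate 2 minus the mean of replicates 1 and 3 (diamonds) and replicate 3 minus replicate 1 (circles). Replicate 2 ran from 0.39 in the bin with the shortest transcripts to -0.42 in the bin with the longest, against 0.03 and -0.03 between the other 2 libraries.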

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

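The removal of the length and GC trend was chosen after the data were seen, and the other alternatives beforehand. The count of genes past the threshold, 0 higher and 0 lower with all 6 libraries, rose mainly under settings that gave vehicle replicate 2 less weight. Leaving out 1 library in turn gave 0 to 47 genes higher and 0 to 122 lower, the upper ends without vehicle replicate 2, and 1 higher and 0 lower without C13 replicate 1. Array weights, which gave vehicle replicate 2 a weight of 0.129, called 18 higher and 24 lower, and removal of the length and GC trend called 15 and 21, all 36 also called without vehicle replicate 2. Quantile normalization called 7 higher, rescaling to TPM 2 and limma without the trend 1, with 0 lower in each, and the cause was not tested. Both pseudocounts, both filters, median-of-ratios scaling and the robust option left 0 and 0. A minimum change of 1 had no calls to remove. The replicate block by title numbers gave 0 and 0 and 12 lists. The titles' numbers did not pair the samples by the rule set (correlations of deviations of 0.089, 0.129 and 0.098), although each library correlated best with its own title number, a hint from the data and not from the design. A replicate block by the numbers of the sample descriptions, which differ from the titles, called 16 higher and 24 lower and 15 lists, and its pairs correlated at -0.101 and 0.098. Vehicle replicate 2 and C13 replicate 1 have no partner by those numbers, so the block takes both out of the comparison and its calls are not a gain from pairing alone.

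Of the 11 lists past the threshold, 0 passed with an estimated correlation and fry called 6 lists, 5 of them shared. The shared lists were NRF2 targets, interferon-stimulated genes, proinflammatory cytokines, immediate early genes and NF-kappaB targets. Antigen presentation, cholesterol synthesis and astrocyte markers failed both tests (fry adjusted p = 0.129, 0.172 and 0.326), as did interferons and receptors, homeostatic markers and stress response genes. Other alternatives called 10 to 15 lists. NRF2 targets, interferon-stimulated genes, proinflammatory cytokines, immediate early genes, antigen presentation, cholesterol synthesis and astrocyte markers passed in all 18 of these, and interferons and receptors, NF-kappaB targets, homeostatic markers and stress response genes were lost in 3, 1, 3 and 1. The NRF2 median ran from 0.33 to 0.56 and the interferon-stimulated median from -0.30 to -0.11. Among these 11 lists and 72 named genes no direction of a test was reversed, but the change of Cxcl10 was 0 under quantile normalization. That setting gives a gene of the same rank in every library the same value, so the 0 can reflect rank alone. Genes named only for the comparison without vehicle replicate 2 were not followed through the alternatives. Of the lists that did not pass, LXR targets passed in 7 of the 18 alternatives, anti-inflammatory genes in 4, chemokines, inflammatory effectors and disease-associated markers in 3 each, glycolysis genes in 2 and lysosome genes in 1. Without that library the median of the MOK and BET list turned from 0.12 to -0.02. Rescaling to TPM moved the median of all genes by 0.126. Among 72 named genes 79 results under alternatives passed where the main one did not. The planned count test on whole reads was not run because whole reads could not be recovered from these FPKM values.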

Other observations

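Tests on the depth and the mesothelial signal of vehicle replicate 2, on both list patterns without that library, on the LPS response as a whole and on the chemokines were chosen only after the results were seen.

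Some genes of haem and iron handling were named after their values were seen, and were not tested as a group. With all 6 libraries neither ferritin gene, Ftl1 or Fth1, passed, as no gene did. Without vehicle replicate 2, Ftl1 passed (limma adjusted p = 0.0311) and Fth1 did not (adjusted p = 0.0655). Slc48a1, a haem transporter gene, had 71.2 ± 11.8 FPKM with vehicle and 104 ± 8.85 FPKM with C13 (SD, n = 3). The iron exporter gene Slc40a1 had 0.937 ± 0.215 and 2.63 ± 0.381 FPKM. Blvrb, which encodes a biliverdin reductase, had 68.9 ± 23.6 and 89.6 ± 5.42 FPKM with overlapping groups, and passed without vehicle replicate 2 (change of 0.68, limma adjusted p = 0.0144). The RNA of NRF2 itself, Nfe2l2, had 93.6 ± 5.22 and 104 ± 3.15 FPKM and did not pass in either comparison.

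Cyp1a1, the gene with the lowest p, is a classical target of the aryl hydrocarbon receptor. A list of its targets was written after the gene was seen to lead, and 8 of 10 were measured. Ahrr, the receptor's repressor, had 1.59 ± 0.196 FPKM with vehicle and 2.73 ± 0.214 FPKM with C13, and Cyp1b1 had 230 ± 62.4 and 296 ± 10.4 FPKM with a large spread. A candidate explanation is that the receptor's targets moved as a group. The median change of the targets other than Cyp1a1 and Nqo1 was 0.24, between the 0.3 that the hypothesis asked for and the 0.1 that would have spoken against it, so the data leave it open. Without vehicle replicate 2 that median was 0.15, nearer to the lower bound.

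Vehicle replicate 2 differed from vehicle replicates 1 and 3 in a graded way with transcript length and GC content, which together explained 41.9% of the variance of its difference across genes, against 2.2% to 5.7% in the other libraries. Removal of that trend lowered the median residual SD from 0.159 to 0.121. A technical origin in the RNA or the library of that sample is a candidate explanation. The estimated depth of vehicle replicate 2 was 1.212 times that of vehicle replicate 1, against 1.20 for vehicle replicate 3. The C13 libraries lay at 1.25 to 1.30, so only sequencing shallower than in the other vehicle libraries is argued against. Keratin genes and Msln also pointed to mesothelial or epithelial cells, but 3 markers that had not prompted the idea (Krt19, Cdh1 and Epcam) differed by a median of 0.137 after the trend was removed, at a median of 2.73 FPKM, too low to decide. The mesothelial markers Upk3b and Lrrn4 were at the floor of 0.01 FPKM in all 3 vehicle libraries. The labels name no difference in animals, culture or handling between vehicle libraries, and none of that kind was tested.

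The rise of NRF2 targets was not carried by that library or its trend. The median change was 0.421 with all libraries, 0.448 without vehicle replicate 2 and 0.452 after removal of the length and GC trend. The libraries argue against a larger share of astrocytes as the main source of the rise. Mean deviations of the NRF2 list were 0.45 and 0.44 in C13 replicates 1 and 2, where those of the astrocyte markers were 0.14 and 1.20. The 14 astrocyte markers together gained 41.9 FPKM and Hmox1 alone 589.7 FPKM, below the bound set against that explanation. That bound cannot decide, since the markers summed to only 96.5 FPKM with vehicle and their gain does not limit what astrocytes add to other genes. An effect of C13 may remain as the hypothesis, untested by an inactive compound or another dose.

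The fall of interferon-stimulated genes likewise had a median of -0.261 with all libraries, -0.258 without vehicle replicate 2 and -0.246 after removal of the trend. The NF-kappaB list had a median of -0.133 and the Toll-like receptor list one of 0.056, the latter -0.031 without vehicle replicate 2, and a weaker response to LPS as a whole stays open, since no library without LPS shows how strongly these lists were induced. The mean of interferon-stimulated minus NF-kappaB genes was -0.125 ± 0.008 in the C13 libraries and 0.00 ± 0.013 in the vehicle libraries (SD, n = 3). Proinflammatory cytokines fell by a median of -0.33, and a weaker response to LPS, in part or as a whole, may account for both falls. A fall of all inflammatory genes alike was not seen. Over the chemokine list alone Cxcl1, Cxcl3 and Cxcl5 rose by 0.40, 0.52 and 0.62, while 5 other members fell. Ifnb1 itself varied too much between vehicle libraries to tell whether less interferon was made.

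Chemokine genes grouped by the receptor of their ligands, CXCR2 (Cxcl1, Cxcl2, Cxcl3, Cxcl5) or CXCR3 (Cxcl9, Cxcl10, Cxcl11), differed in their mean change. Cxcl11 is annotated as a polymorphic pseudogene, so its RNA need not yield a working ligand, and the values concern RNA only. Cxcl2 had 857 ± 53.5 and 879 ± 32.0 FPKM, a change of 0.04, and Cxcl10 did not pass over the chemokine list alone (adjusted p = 0.0839). Against the vehicle mean, the CXCR2 ligands changed by a mean of 0.39 and the CXCR3 ligands by -0.55 in the C13 libraries, a difference of -0.942 that had the same sign in each of the 3 C13 libraries (-0.64, -0.999 and -1.19). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows, so the p under 0.05 asked for could not be reached. These genes and that rule were chosen after the values were seen. Ccl3, Ccl12 and Ccl22, in neither group, also fell over the chemokine list alone (changes of -0.40, -0.87 and -0.83). Whether Ccl3, Ccl12 and Ccl22 depend on interferon was not tested. The hypothesis that interferon-dependent chemokines fell while others did not therefore cannot be extended to chemokines in general. It may be held as open only for the CXCR2 and CXCR3 groups.

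The 6 libraries can be split into 10 pairs of 3, too few for a share under 0.05. The real split had 0 genes higher and 0 lower, which any split equals, so that all 10 of the 10 had at least as many and the count tells nothing. The highest other had 2. For lists the real split called 11 and the highest other 12, and 2 of the 10 splits called 11 or more. The other split with so many set vehicle replicate 1 with C13 replicates 2 and 3 against the rest. For the astrocyte markers 3 of the 10 splits, the real one among them, gave a p as low as the real one.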
